A study of Homo sapiens with 6 samples.

How the data were processed

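RNA from 6 samples of HMLE cells, 3 of the control line and 3 of the Twist line, was measured on Affymetrix Human Genome U133 Plus arrays with 1 array per group. The groups were DMSO, Cmp302 at 5 µM and Cmp302 at 10 µM in each line, as given by the sample titles. Per the labels' protocols cells were treated for 6 h, whereas the source names and treatment tags give 2 µM for 4 h and 8 h, so the levels were coded 0, 1 and 2 and the nature of the step was left open. The deposited values are log2 signals, judged from their range and distribution because the labels name no unit. The analysis had been laid out for linear signal, and its scaling and floor were therefore applied on the log2 scale. GCOS 1.2 is named per the submitters' processing notes, and the method of background correction, summarisation and normalisation is not given in the sources used here. The percentiles of the 6 deposited log2 columns lay close together, with medians from 3.69 to 3.74.

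Of 54675 probe sets, 62 Affymetrix controls were left out. Each array was shifted so that the median log2 ratio to the mean array over the brighter part of the probe sets was 0, with offsets from -0.03 to 0.01. Signals under a floor at the median of all values, 3.71 log2 units, were set to the floor. A gene was read by the probe set with the highest mean signal among those named with 1 symbol, which gave 19775 genes from 41091 probe sets. The 1801 probe sets with several symbols and 11721 with none were not used. A total of 12730 genes lay above the floor on any array and 10787 on all 6. A change was the difference of log2 signals between arrays, and a gene counted as higher or lower past 2-fold if it lay above the floor on at least 1 array compared. Where 1 side lay at the floor the change is a bound. With 1 array per group these differences carry no error, and the spread between the probe sets of a gene is given as their SD or range for named genes in which it was widest.

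Tests used limma 3.58.1 in R 4.3.3 with the signal trend in eBayes and Benjamini-Hochberg adjustment at 0.05, over 12478 genes above the floor on at least 2 arrays. One fit had treatment as a factor and line as the tested term, and another had line, level and their interaction, which gave the trend in each line and the difference between them. Both leave 2 residual degrees of freedom. The 24 gene lists, with 428 symbols of which 382 were matched to a gene on the array, were ATF4 and CHOP stress targets, amino acid supply and tRNA charging, ER chaperones and folding enzymes, ER-associated degradation and stress sensors, ER translocation and trafficking, cytosolic heat shock, NRF2 oxidative stress, cholesterol and fatty acid synthesis, p53 targets, cell cycle, immediate early genes, NF-kB and inflammatory genes, interferon response, cell death regulators, autophagy and lysosome, hypoxia and glycolysis, metallothioneins, mesenchymal markers, secreted extracellular matrix, epithelial junction markers, basal and luminal epithelial markers, blood, endothelial and fat cell markers, and ribosomal proteins. A list median was set against 10000 random lists of the same size matched on signal in 20 bins, and stood apart below the 2.5th or above the 97.5th percentile, which is a description of these arrays and not a p-value.

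Overlaps between levels were set against independent lists and against 100 simulations with no effect and a shared DMSO array, with noise from the residuals of the additive fit. The groups, comparisons, lists, the rule for named genes and the alternatives were fixed before the data were examined, apart from those named as chosen later. The rule took the 10 highest and 10 lowest genes past 2-fold, at both levels for the compound, among genes above the floor on all arrays compared with no probe set going the other way. It added the 4 members of each list with the widest change and 10 genes of EMT and stress responses. The fits were tested on simulated data before use. A simulated step of 1 log2 unit was recovered for 88% of changed genes between lines, for 96% in the Twist-line trend and for 62% in the difference of trends, and a step of 2 for 100% in each, with 8, 12 and 6 false calls among 12478 genes. These rates are for simulated data only. In the deposited data DDIT3, with a difference in trend of 2.84 log2 units per level, was not called, as its change departed from a straight line.

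Alternatives were the deposited scaling, quantile normalization, the floor at the 35th or 65th percentile, the median over probe sets, leaving out probe sets with suffixes for cross-hybridisation, no filter, the levels coded 0, 1 and 1, and leaving out each array or treatment pair. Chosen after seeing the data were the quality-matched change, in which each gene's slope on the 3' to middle contrast over the control-line arrays, times the difference in the contrast, was subtracted, its list medians over members above the floor on those 3 arrays, and a count of genes 2-fold outside the range of all 4 other arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.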

Results

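Gene expression was measured in HMLE cells, an immortalised line of human mammary epithelial cells. A control line had been infected with a retrovirus for a hairpin against GFP, and a Twist line with a retrovirus for Twist, a transcription factor that drives the epithelial-mesenchymal transition (EMT). Each line received the solvent DMSO or Cmp302, a small molecule known here by its code name only, at 2 levels. Total RNA was hybridised to 6 Affymetrix U133 Plus arrays, 1 per group. With 1 array per group, no difference between arrays has a replicate check, and the number of arrays limits the precision. Genes are called higher or lower where they passed a fixed 2-fold threshold, which is 1 on the log2 scale, and "rose" and "fell" are kept for genes that passed a test over all 6 arrays. Of each list the 4 members with the widest change were named by rule, and further members named below were chosen after their values were seen. The titles and the treatment protocol name the levels as 5 µM and 10 µM for 6 h, whereas the source names and treatment tags read 2 µM for 4 h and 2 µM for 8 h. The arrays are named here by their titles, and whether the step between levels was one of dose or of time is left open.

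Between 11646 and 11841 of 19775 genes lay above the signal floor on each array. Across genes, which are not independent replicates, signals correlated at 0.993 to 0.996 among the control-line arrays, at 0.956 to 0.994 among the Twist-line arrays and at 0.889 to 0.910 between lines. The first principal component held 81.8% of the variance and the next 14.5%. The arrays also differed in the contrast between the 3' and middle probe sets of GAPDH and ACTB, a common measure of RNA integrity and labelling. Its mean was 0.28, 0.45 and 0.84 log2 units on the DMSO, 5 µM and 10 µM arrays of the control line. In the Twist line it was 0.96 on the DMSO array, 0.36 at 5 µM and 0.45 at 10 µM. The Twist DMSO array, the baseline of each compound change in that line, had the highest value of the 6. For this reason quality-matched values are printed beside the Twist-line groups below, in which each gene's slope on this contrast over the 3 control-line arrays, times the difference in the contrast, was subtracted. That adjustment was chosen after the data were seen, and it cannot move a gene that lies at the floor in the control line. In that line the contrast went up with the compound level, so a slope on it holds any response to Cmp302 there as well as quality.

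The comparison of the lines under DMSO asked how Twist had altered the cells. TWIST1 itself had signals of 10.70, 10.51 and 10.48 log2 units in the control line and 11.57, 11.96 and 11.35 in the Twist line, a difference of 0.87 under DMSO. It was read by 1 probe set, and a viral cDNA lacking the probed part, or from another species, would not be seen by it, so this level may say little about the labels. The epithelial programme was lower across the board in the Twist line. CDH1, which encodes E-cadherin, had 13.24 log2 units in the control line and lay at the floor of 3.71 in the Twist line, a log2 change of at most -9.53. Of 26 measured epithelial junction genes, 25 were lower by 2-fold or more, with a median change of -6.95. They included EPCAM, the splicing regulator ESRP1 (-8.69) and the desmosomal gene DSP (-6.96). All 10 measured basal keratinocyte-type genes were lower, with a median of -8.05, led by the keratins KRT14 (-9.88), KRT5 (at most -9.67) and KRT15 (-8.58). Among 6 measured luminal genes, 5 were lower and GATA3 was higher by 1.05.

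Mesenchymal genes were higher in the Twist line. Of 25 measured members, 20 were higher and 1 was lower, with a median of 3.19. The EMT transcription factors ZEB1 and ZEB2 were higher by 6.93 and 6.95, and PRRX1, at the floor in the control line, by at least 8.96. VIM, encoding vimentin, was higher by 1.52, whereas TAGLN had a change of -2.62. Of 18 measured genes of secreted extracellular matrix, 11 were higher and 1 lower (median 2.76), with COL6A1 higher by 7.91 and COL5A2 by 4.21. The 2 probe sets of COL6A1 above the floor differed, with an SD of 4.46 log2 units between them. Over the whole array 1488 genes were higher and 1687 lower among 12510 measured. Outside the lists, the 10 highest ranked genes included the proteoglycan gene SRGN (8.05), the sulfotransferase gene SULT1E1 (7.96), GNG11 (7.77) and KCNMA1 (7.04). The lowest included the cornified envelope gene SPRR1A (-9.41), PLEK2 (-8.39) and PPP1R14C (-8.33).

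On the DMSO arrays inflammatory genes were lower in the Twist line as well. Of 15 measured NF-kB and inflammatory genes, 9 were lower and 0 higher, with a median of -1.48 at the 0.03rd percentile of 10000 random lists matched on signal. The cytokine gene IL1A was at the floor in the Twist line (at most -6.55), PTGS2, encoding cyclooxygenase 2, had a change of -4.32, and ICAM1, encoding an adhesion molecule, of -4.16. Interferon response genes had a median of -0.51 (1.94th percentile), with IFIT1 at -3.36, and immediate early genes a median of -0.87 (0.07th), with EGR3 at -6.50. ER chaperones had a median of -0.41 (1.38th percentile) and ribosomal protein genes, kept as a control list, one of -0.65 (0.39th). These medians share the Twist DMSO array with its 3' to middle contrast of 0.96. That array is also the baseline of the compound changes in the Twist line, so a low signal on it makes those changes higher. The markers of blood, endothelial and fat cells had a median of 1.32 over 4 measured genes, with the endothelial gene PECAM1 higher by 3.59 and the fatty acid carrier FABP4 by 2.71, but the median was -0.07 when the median over each gene's probe sets was used. The other lists had medians inside the middle 95% of random lists. These were ATF4 and CHOP targets (-0.33), amino acid supply (-0.14), ER-associated degradation (-0.35), ER translocation (0.21), heat shock (0.00), NRF2 genes (0.03), cholesterol synthesis (-0.09), p53 targets (0.44), cell cycle (0.29), cell death (0.10), autophagy (-0.29), hypoxia and glycolysis (-0.34) and metallothioneins (0.10).

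With treatment as a factor in a limma fit over the 6 arrays, 1705 of 12478 genes were higher and 1854 lower in the Twist line at an adjusted p of 0.05. TWIST1 was among the higher ones (1.06 ± 0.21 log2 units, SE, adjusted p = 0.017). Of the mesenchymal genes 22 of 25 were higher and 2 lower, and the counts adjusted over the list alone were again 22 and 2. Of the junction genes 25 of 26 were lower (25 adjusted over the list alone), of the basal genes 10 of 10 (10), and of the luminal genes 5 of 6 (5). For extracellular matrix 12 were higher and 2 lower of 18 (13 and 2 adjusted over the list alone). The lists whose medians were low under DMSO had few calls over the 3 treatments. NF-kB genes had 1 higher and 2 lower of 15 (1 and 2 adjusted over the list alone), interferon genes 1 and 2 of 13 (1 and 2), immediate early genes 2 and 4 of 14 (2 and 4), ER chaperones 1 and 0 of 20 (1 and 0) and ribosomal proteins 0 and 0 of 14 (0 and 0). This fit averages over the 3 treatments, so a gene that differed from DMSO with Cmp302 in 1 line only can be called. Of the ATF4 and CHOP targets 6 of 19 were higher (6 adjusted over the list alone). DDIT3 was among them (4.43 ± 1.11 log2 units, SE, adjusted p = 0.036), although its difference under DMSO was 0.90. The fit has 2 residual degrees of freedom, and its spread is the difference between lines across treatments, not replicate spread. Without the DMSO pair it called 3561 higher and 3682 lower genes, with the floor at the 65th percentile 1124 higher, and with no filter on low signals 832 higher.

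The question put to the Twist line was what Cmp302 did to cells that had passed through EMT. Targets of ATF4 and CHOP, the transcription factors of the integrated and ER stress responses, stood out. All 19 measured members were above their DMSO value at both levels, and 12 were past 2-fold at each level. The list median was 1.86 log2 units at 5 µM and 2.08 at 10 µM, above all 10000 matched random lists. DDIT3, which encodes CHOP, was higher by 5.28 and 5.80 log2 units, or 38.8-fold and 55.8-fold. TRIB3, a pseudokinase induced by ATF4 and CHOP, was higher by 4.96 and 5.64, the stress transcription factor ATF3 by 4.55 and 5.54, the sestrin gene SESN2 by 4.74 and 5.20 (SD 0.95 between 2 probe sets), and CHAC1, encoding an enzyme that breaks down glutathione, by 3.64 and 4.81. PPP1R15A, whose product reverses eIF2-alpha phosphorylation, was higher by 3.10 and 3.70, and GDF15 by 2.19 and 2.98. ATF4 itself was higher by 1.08 at 5 µM, and by a like amount at 10 µM, but was under 2-fold at both levels when quality-matched (0.92 and 0.97). Its signal on the Twist DMSO array was 12.68, against 13.50 on the control-line DMSO array. In the control line the same list had medians of -0.10 and -0.12, and DDIT3 differed from DMSO by 0.37 and 0.13. Over the 17 members above the floor on all 3 control-line arrays, which can carry the quality matching, the Twist-line medians were 2.19 and 2.90, and quality-matched they were 2.14 and 2.70. Of these 17, 11 were past 2-fold at each level, and 9 and 11 when quality-matched. The median size of the correction was 0.14 at 10 µM. Some of the 17 lay near the floor in the control line, such as CHAC1 (4.15 under DMSO), which bounds a downward slope.

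**Figure D1:**
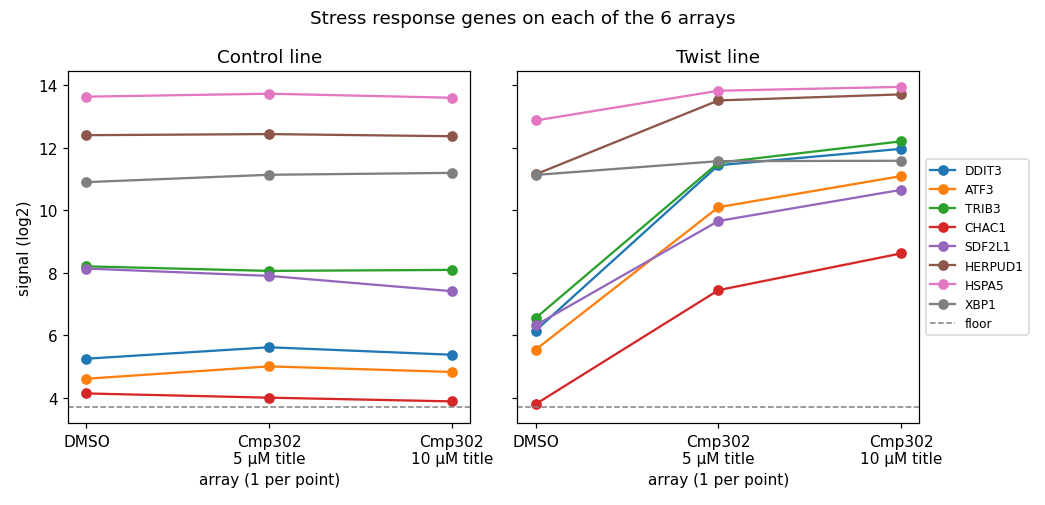
Log2 signal of 8 stress response genes on each of the 6 arrays, with the control line on the left and the Twist line on the right and 1 point per array. In the Twist line DDIT3 went from 6.16 under DMSO to 11.44 and 11.96 at the 2 compound levels, while in the control line it lay between 5.26 and 5.62. The dashed line is the floor at 3.71.

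Genes that supply amino acids and charge tRNA, many of them ATF4 targets, were higher as well. Of 23 measured, 10 were past 2-fold at 5 µM and 11 at 10 µM, and the medians were 0.80 and 0.89 (quality-matched 0.69 and 0.86, with 7 and 10 past 2-fold). The transporter subunit SLC3A2 was higher by 1.88 and 2.46, and the tRNA synthetase genes AARS1 by 2.07 and 2.42, WARS1 by 1.69 and 2.14 and GARS1 by 1.85 and 1.96. These synthetase genes had negative changes in the control line, for GARS1 -0.455 and -0.903. The quality matching therefore lowers their Twist-line changes. PSAT1, PSPH and SLC38A2, on the same list, had changes of -0.11, -0.44 and -0.31 at 10 µM. ER chaperones and folding enzymes had medians of 0.62 and 0.92 (quality-matched 0.51 and 0.64), with 8 and then 9 of 20 past 2-fold (quality-matched 6 and 8). SDF2L1 was higher by 3.33 and 4.32, the HSP40 co-chaperone DNAJB11 by 1.78 and 2.31, HYOU1 by 1.81 and 2.19 and CRELD2 by 1.64 and 2.01. HSPA5, which encodes the ER chaperone BiP, had changes of 0.95 and 1.07, past 2-fold at 10 µM. Its Twist DMSO signal of 12.87 was the lowest of the 6 arrays. Control-line signals were 13.59 to 13.72, and the Twist-line signal at 10 µM was 13.94. CANX and CALR had changes of 0.20 and 0.07 at 10 µM. Another probe set of HSPA5 gave 2.84 at 10 µM (SD 1.25 between the 2). ER-associated degradation and stress sensor genes had medians of 0.57 and 0.61 (quality-matched 0.34 and 0.50). HERPUD1 was higher by 2.36 and 2.55, ERN1, encoding the sensor IRE1, by 1.55 and 2.42, and FICD, at the floor under DMSO, by at least 2.13 at 10 µM, whereas EDEM3 had changes of -1.30 and -1.68. XBP1 differed by 0.44 and 0.45. The 18 measured genes of ER translocation and trafficking had medians of -0.30 and -0.30, which became 0.36 and 0.49 with the median over each gene's probe sets and were -0.14 and -0.19 quality-matched.

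Inflammatory genes were the other group far from DMSO in the treated Twist line. All 15 measured NF-kB and inflammatory genes were above DMSO at both levels, 10 and then 11 of them past 2-fold, with medians of 1.57 and 2.22 (quality-matched 1.18 and 1.95). ICAM1 was higher by 4.61 and 5.36 (3.66 at 10 µM on its other probe set), the cytokine gene IL6 by 3.94 and 5.37, PTGS2 by 3.61 and 4.52 and the cytokine gene LIF by 3.45 and 3.72. The NF-kB inhibitors NFKBIA and TNFAIP3 were higher by 2.18 and 2.17 at 10 µM. At 10 µM the signals of ICAM1, PTGS2 and LIF lay above those of the control line at the same level, from a lower start. ICAM1 went from 4.84 to 10.20, against 8.92 on the control-line array at 10 µM. Interferon response genes had medians of 0.31 and 0.67 over 12 measured (quality-matched 0.39 and 0.85). IFIT2 was higher by 3.51 and 4.57 and IFIT1 by 2.71 and 4.34, with IFI44L at -0.75 and -1.48. OASL, an interferon-inducible gene outside the list, was higher by 4.15 and 5.39. Immediate early genes had medians of 0.47 and 0.53 (quality-matched 0.30 and 0.45), with MYC higher by 1.19 and 1.37. Quality-matched, 0 members of that list, MYC included, were past 2-fold at either level.

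Outside these groups, CLDN1, encoding the tight junction protein claudin-1, was higher by 4.71 and 5.28 and HEY1, a Notch target, by 3.75 and 4.11. CLDN1 apart, no measured epithelial junction gene was higher by 2-fold, and CDH1 stayed at the floor on all 3 Twist-line arrays. VIM had changes of 0.61 and 0.57 on its brightest probe set and one of -1.55 at 10 µM on another. NRF2 oxidative stress genes had medians of 0.35 and 0.44 (quality-matched 0.15, inside the middle 95% of random lists, and 0.30), with HMOX1, encoding heme oxygenase 1, higher by 2.53 and 3.03 and SLC7A11, the cystine transporter, by 1.51 and 1.88. Autophagy and lysosome genes had medians of 0.40 and 0.36, the second inside the middle 95% of random lists, with SQSTM1 higher by 1.24 and 1.46. Quality-matched the list medians were 0.31 and 0.33, both outside that range. Among the 10 lowest ranked genes were EEIG2 (-3.09 and -4.34), the cadherin gene CDH6 (-2.65 and -3.53), PTGR2 (-2.54 and -2.92), the cell cycle repressor gene E2F8 (-2.12 and -3.09), the apoptosome gene APAF1 (-2.12 and -2.63), LPCAT2 (-2.08 and -2.28, with an SD of 0.85 over 4 probe sets) and the growth arrest gene GAS1 (-2.07 and -3.42). Cell cycle genes had medians of -0.26 and -0.37 (quality-matched -0.21 and -0.31), with KIF20A at -1.11 and -2.04 and CCNE2 at -1.28 and -1.68. Ribosomal protein genes had medians of 0.68 and 0.68, which were 0.22 and 0.22 quality-matched, inside the middle 95% of random lists.

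Besides the cell cycle and ER translocation lists, those that stayed inside the middle 95% of random lists at both levels in the Twist line, given at 10 µM, were heat shock (-0.08), cholesterol synthesis (0.12), p53 targets (0.28), cell death regulators (0.00), hypoxia and glycolysis (-0.04), metallothioneins (0.27), mesenchymal markers (-0.28), extracellular matrix (-0.01), epithelial junctions (-0.12), basal (-0.11) and luminal markers (0.17), and blood, endothelial and fat cell markers (-0.27). Heat shock turned positive with the median over probe sets (0.53), and its highest member was CRYAB at 1.45. With quantile normalization the extracellular matrix and cell death medians changed sign, to 0.02 and -0.08. Quality-matched, the cell cycle list lay below the 2.5th percentile at both levels, p53 targets had medians of 0.43 at 5 µM (99.8th percentile) and 0.34 at 10 µM, and the other 12 of these lists stayed inside.

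**Figure D2:**
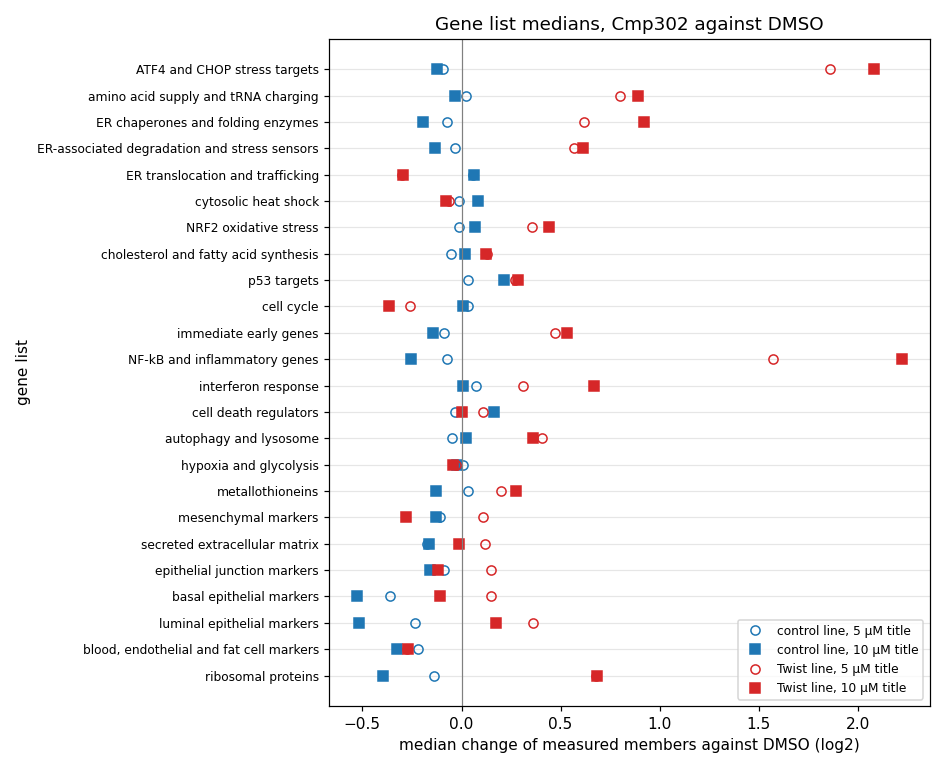
Median log2 change against DMSO of the measured members of each of the 24 gene lists, with open circles for 5 µM and squares for 10 µM, blue for the control line and red for the Twist line. The NF-kB list (2.22) and the ATF4 and CHOP list (2.08) lie farthest to the right at 10 µM in the Twist line, while control-line medians lie between -0.53 and 0.22.

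Counted over all genes, 506 were higher and 595 lower at 5 µM among 11868 measured in the Twist line, and 959 and 1009 at 10 µM among 11931. At both levels 474 were higher and 552 lower, against 41.0 and 50.8 for independent lists. Arrays simulated with no effect and a shared DMSO array gave 67.1 and 67.6 on average, with maxima of 85 and 92, but their noise was taken from residuals that hold the difference between lines, so neither value is a clean one for no change, and part of the overlap may come from the shared DMSO array. Quality-matched, 238 of the 474 and 279 of the 552 kept their 2-fold change. On both treated arrays 178 of the higher and 109 of the lower genes lay 2-fold outside the range of all 4 other arrays, and 10 of the 19 ATF4 and CHOP targets were among them. Fewer members of the other stress and inflammatory lists were. These were 3 of 23 amino acid and tRNA genes, 2 of 20 ER chaperones, 1 of 16 ER-associated degradation genes and 3 of 15 NF-kB genes. Since 3 of the 4 other arrays are of the other line, a difference between lines affects this count. A gene meets it more easily where that difference runs with the compound change, and less easily where it runs against it. ICAM1 and CLDN1, lower in the Twist line under DMSO and higher with the compound, were not counted. With the median over probe sets, 319 genes were lower at 5 µM, 653 at 10 µM and 293 at both.

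A limma trend over the levels called 1353 genes that rose and 1421 that fell in the Twist line, of 12478 tested. DDIT3 rose by 2.90 ± 0.58 log2 units per level (SE, adjusted p = 0.028), TRIB3 by 2.82 ± 0.52 (adjusted p = 0.025) and HSPA5 by 0.54 ± 0.12 (adjusted p = 0.036), each above DMSO on both treated arrays. Of the ATF4 and CHOP targets 14 of 19 rose (17 adjusted over the list alone), of the amino acid and tRNA genes 11 of 23 (15), of the ER chaperones 11 of 20 (12), and of the NF-kB genes 14 of 15 (14). ER-associated degradation had 6 that rose and 1 that fell of 16 (8 and 1 adjusted over the list alone), interferon response 6 and 1 of 13 (7 and 1), immediate early genes 5 and 0 of 14 (5 and 0) and NRF2 genes 4 and 0 of 13 (5 and 1). Among cell cycle genes 0 rose and 8 fell of 25 (2 and 10 adjusted over the list alone), among mesenchymal genes 0 and 5 of 25 (0 and 5), with COL1A2, CDH11 and DCN falling, and among extracellular matrix genes 1 and 4 of 18 (2 and 6). Of the ribosomal protein genes 3 of 14 rose (10 adjusted over the list alone). The spread in this fit is the departure from a straight line over 2 residual degrees of freedom, not replicate spread. The calls depended on every array but 1, the Twist 5 µM array. Without any 1 of the Twist-line arrays the spread comes from the control line alone, so this does not set the 5 µM array apart. With the Twist 5 µM array left out 1468 rose and 1756 fell, whereas with any of the 3 control-line arrays, the Twist DMSO array or the Twist 10 µM array left out 0 genes were called. With no filter on low signals 8 rose and 9 fell, and with the 2 compound levels taken as alike 2227 fell.

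The same comparison in the control line asked how far the compound acted on cells that had not passed through EMT. At 5 µM 7 genes were higher and 8 lower among 11968 measured, and at 10 µM 24 and 31 among 11975. These small counts moved with the processing. Without probe sets that can cross-hybridise they were 12 and 8 and then 47 and 22, with quantile normalization 30 and 19 at 10 µM, and with the median over probe sets 5 and 2 and then 31 and 19. None of the 10 highest-ranked genes of the Twist line passed 2-fold here at either level, and CLDN1, at -0.28 and -0.80, was the farthest of them from DMSO. The genes higher at both levels were GBP6 (1.72 and 1.37), CYP1B1, encoding a cytochrome P450 of the aryl hydrocarbon response (1.16 and 1.56), and a transcript of the MIR34A locus. Lower at both were POU2F3 (-1.33 and -1.62), PSPN (-1.17 and -1.32), PTAFR (-1.35 and -1.14), TUBAL3 (-1.08 and -1.48) and SLC6A11, which lay outside the naming rule and was named after its values were seen. Independent lists would share 0.014 and 0.021 genes, but both changes share 1 DMSO array. The no-effect simulation gave 67.1 and 67.6 here too, because its noise was taken from residuals that hold the difference between lines, so no usable value for no change stands beside these 3 and 5 genes. MYC had changes of -0.48 and -1.48. The highest gene at 10 µM was COL1A1 (0.13 and 2.61), a gene chosen after its values were seen, of which the 2 other probe sets above the floor had 5.79 and 4.17 under DMSO and 5.77 and 4.35 at 10 µM.

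Among the lists in the control line, basal epithelial genes had medians of -0.36 and -0.53 (0.01st percentile at both levels), with KRT5 at -0.56 and -0.79. Luminal genes were at -0.24 and -0.52, ribosomal proteins at -0.14 and -0.40 and ER chaperones at -0.08 and -0.19, the last 3 below the 2.5th percentile at 10 µM. Over the same arrays the 3' to middle contrast went from 0.28 to 0.45 and 0.84. Extracellular matrix was at -0.18 at 5 µM (1.11th percentile) and -0.16 at 10 µM. The other lists at 10 µM lay inside the middle 95% of random lists, from blood, endothelial and fat cell markers at -0.32 to p53 targets at 0.22. Over all genes the limma trend called 0 up and 0 down in this line, with 937 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.621. Adjusted over the list alone, 2 immediate early genes, 1 hypoxia and glycolysis gene and 1 luminal gene fell, and 0 were called in the other lists. With no filter on low signals it called 3 and 11 over all genes. A p that misses the threshold does not show that the line did not respond.

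From 5 µM to 10 µM in the Twist line 70 genes were higher and 60 lower among 11813, and 39 were higher with the floor at the 65th percentile. All 15 NF-kB genes lay above their 5 µM value at 10 µM, 2 of them by 2-fold, with a median of 0.53, and IL6 gained 1.43 and RELB 1.26. Interferon genes had a median of 0.34, with IFIT1 higher by a further 1.63, ATF4 and CHOP targets one of 0.22 and ER chaperones one of 0.19, each in the top 2.5% of random lists. Amino acid, ER-associated degradation, heat shock and NRF2 genes were in the top 2.5% as well. So was the ribosomal protein control list, with a median of only 0.02. DDIT3 stood 5.28 above DMSO at 5 µM and gained 0.52 more. In the control line the step gave 5 higher genes, COL1A1, FURIN, DOCK10, HOXB9 and ABCB8, and 11 lower among 11957. With the floor at the 65th percentile these were 3 and 7, and with the median over probe sets 1 was higher.

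The series title calls the compound selective for EMT and says that it induces ER stress. The difference between lines is the comparison behind the selectivity. The Twist-line change exceeded the control-line change by 2-fold or more for 1020 genes at 5 µM and 1701 at 10 µM, and lay 2-fold or more below it for 992 and 1558, among 12636 and 12688 measured. For the lower genes the counts with the median over probe sets were 543 and 927. TRIB3 differed by 5.10 and 5.76, DDIT3 by 4.91 and 5.68, ICAM1 by 4.79 and 5.44, OASL by 4.48 and 5.96 and CLDN1 by 4.98 and 6.09. In the other direction EEIG2 differed by -3.27 and -3.57, the von Hippel-Lindau gene VHL by -2.88 and -2.88, PTGR2 by -2.80 and -2.68 and ZC3HAV1L by -2.58 and -2.99. At 10 µM the median difference was 2.60 for NF-kB genes (13 of 15 past 2-fold), 2.08 for ATF4 and CHOP targets (13 of 19), 1.01 for amino acid and tRNA genes (12 of 23), 0.99 for ER chaperones (10 of 20), 0.87 for ER-associated degradation (7 of 16) and 0.74 for NRF2 genes (5 of 14). For ribosomal proteins, the control list, it was 1.16 (8 of 14), more than for the amino acid, chaperone, degradation and NRF2 lists, and the Twist DMSO array is a baseline of all these differences. From DMSO to 10 µM the 3' to middle contrast went from 0.28 to 0.84 in the control line. In the Twist line it went from 0.96 to 0.45. The differences between lines hold both shifts, and no quality-matched difference was computed. The limma test of the difference in trend called 93 genes higher and 99 lower of 12478. For 19 and 23 of them 1 line lay at the floor on all 3 arrays, which fixes its slope, so those calls do not compare responses. IFIT1 (2.10 ± 0.23 log2 units per level, SE, adjusted p = 0.036) and RELB (1.69 ± 0.13, adjusted p = 0.035), both above the floor on all 6 arrays and above DMSO on both treated Twist-line arrays, were among the other calls. DDIT3 was not (2.84 ± 0.82, adjusted p = 0.068), nor TRIB3 (2.88 ± 0.73, adjusted p = 0.059) or ATF3 (2.66 ± 0.62, adjusted p = 0.055). These genes reached most of their change at 5 µM and so departed from a straight line. Of the ATF4 and CHOP targets 0 of 19 were called and 15 adjusted over the list alone, of the ER chaperones 0 of 20 and 11, and of the NF-kB genes 3 of 15 and 14. With the 2 levels taken as alike the test called 1565 and 1738 genes. It called 1021 and 1174 without the Twist 5 µM array and 0 without any one of the 5 other arrays. Where a Twist-line array is left out, whichever it is, the test takes its spread from the control line alone. It called 239 and 214 with the floor at the 35th percentile, 21 and 22 at the 65th, 180 and 175 without the probe sets that can cross-hybridise, 6 and 4 with no filter, and 59 lower ones with the median over probe sets.

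Between the lines, the changes at 10 µM were negatively correlated across 10787 genes (r = -0.411, and -0.468 at 5 µM), and genes are not independent replicates. Past 2-fold at 10 µM, 1 gene was higher in both lines (RABGEF1P1) and 4 were lower in both (GSN, INTS3, LPCAT4 and TSPAN14), against 2.05 and 2.79 for independent lists. Moving in opposite directions were 5 genes higher in the control line and lower in the Twist line, among them AP1S3 and MCM3AP-AS1, and 6 lower in the control line and higher in the Twist line, among them MYC, HSPB1, TUBB and MGST3. The 3' to middle contrast also moved in opposite directions in the lines, and quality-matched MYC was not past 2-fold in the Twist line.

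**Figure D3:**
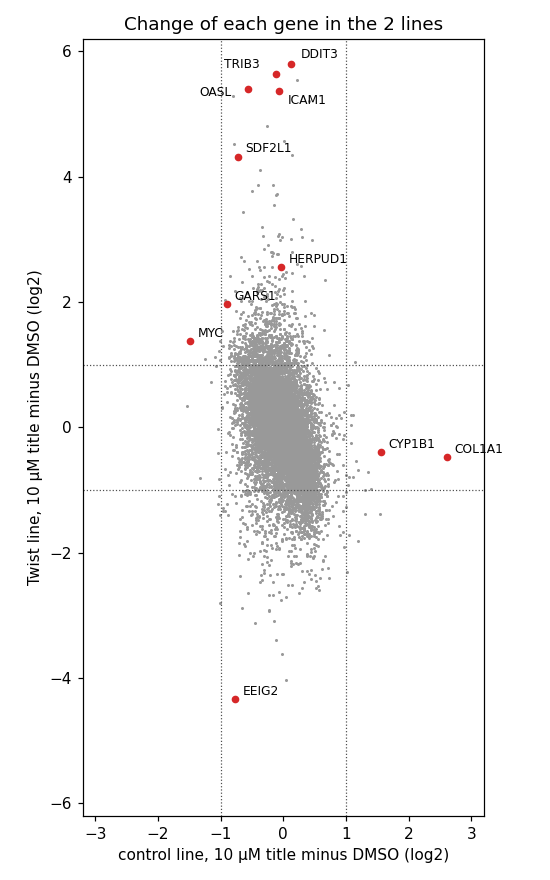
Log2 change from DMSO at 10 µM for each of 10787 genes above the floor on all 6 arrays, with the control line on the horizontal axis and the Twist line on the vertical axis. Each point is 1 gene, dotted lines mark 2-fold, and named genes are in red. The cloud is taller than wide (SD 0.78 against 0.32) and tilts downward (r = -0.411), with DDIT3 at 5.80 in the Twist line and 0.13 in the control line.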

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

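The tests of RNA quality and of mixed RNA in this part were chosen only after the result was seen, and the splits of the arrays were planned.

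GAS1 had a different trend over the compound levels in the 2 lines in the limma test (-1.71 log2 units per level, adjusted p = 0.036). The gene lay at the floor on all 3 control-line arrays, so this value is its Twist-line slope and shows no difference in response between the lines. The same test called 15 members of the lists, among them RELB (1.69), IFIT1 (2.10), ERN1 (1.22) and THBS1 (-1.21), which lay above the floor on all 6 arrays. For 9 lists the median change had opposite signs in the 2 lines at both levels, and this difference was not tested on the medians. The differences in change at 10 µM between the lines were 2.60 for NF-kB and inflammatory genes, 2.08 for ATF4 and CHOP targets, 1.16 for ribosomal proteins, 0.99 for ER chaperones, 0.87 for ER-associated degradation, 0.75 for immediate early genes, 0.55 for luminal markers, -0.36 for ER translocation and -0.40 for cell cycle genes. For ER translocation the Twist-line medians turned positive with the median over probe sets (0.36 and 0.49).

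The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 3559 genes between the lines and 192 genes in the difference of trends, and the highest of the other splits called 0 in each case, so 1 of 10 splits reached each real count. Every other split mixes the lines, so the large difference between lines enters its spread. Their counts of 0 therefore say nothing about the real counts.

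Higher ATF4 and CHOP targets and ER chaperones in the treated Twist line were the first pattern weighed. Lower RNA integrity of the Twist DMSO array, whose 3' to middle contrast was 0.96, was tested as an explanation. Over members above the floor on all 3 control-line arrays, the quality-matched median at 10 µM was 2.70 for 17 ATF4 and CHOP targets (2.90 before) and 0.643 for 20 chaperones (0.92 before), both in the top 2.5% of matched random lists, which argues against quality alone with no response to Cmp302 in either line. The contrast went up with the compound level in the control line, so a response there that hid an effect of quality stays open. The biological candidate, an ER stress response to Cmp302 in cells with Twist, may account for both groups. The series title names ER stress as an effect of the compound, so this candidate did not arise from these values alone. It was not tested and rests on 1 array per group.

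The next pattern was the wide change of genes in the treated Twist line. Of 928 genes above the floor on all 6 arrays and past 2-fold at both levels, 420 (45.3%) stayed so when quality-matched, which argues against quality as the whole cause with no response to Cmp302 in either line. As part of the cause RNA quality stays open, since in the control line the contrast and the compound level went up together. Changes in the 2 lines at 10 µM were negatively correlated across genes (r = -0.411), as a quality trend running in opposite directions would give, while the contrast between the 3' and 5' ends on the Twist DMSO array was clearly highest for ISGF3A (1.93, next 1.22), barely for ACTB (1.72, next 1.68) and not for GAPDH (0.43, against 0.47 and 0.45 on the treated Twist arrays). With quality matched, the ribosomal protein median went from 0.68 to 0.22 at 10 µM, so a response of these genes to the compound and the RNA quality cannot be told apart.

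The last pattern was COL1A1 in the control line, 2.61 log2 units higher at 10 µM on the probe set with the highest signal. RNA of Twist cells in that sample, at the 17.3% share that COL1A1 would need, predicts a median change of 3.86 in 123 genes at the floor in the control line and 16-fold or more above it in the Twist line. Their median was 0 and 0 of them were higher by 2-fold, which argues against it. The 4 other probe sets of the gene did not follow, with the 2 above the floor going from 5.79 to 5.77 and from 4.17 to 4.35, which argues against a change of that size in all its transcripts. A fault of the first probe set and a response of a transcript that it alone reads stay open.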

How the results depend on the processing

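The quality-matched changes and the count outside the range of the 4 other arrays were chosen after seeing the data, and the other alternatives were planned. Of the alternatives to counts past 2-fold, 114 stayed within 1.5 times and 26 did not. For limma counts these were 62 and 42, for list medians 715 stayed and 98 moved, and for named genes 984 and 150, with 1 list and 1 gene reversed, which here means a sign change of a list outside the middle 95% of random lists or of a gene past 2-fold. Medians inside that range, such as ER translocation, changed sign in further cases. Except where the construction is named, the cause was not tested. Signals near the floor limit all values, and a change from the floor is a bound.

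With the floor at the 65th percentile the control line had 3 higher and 5 lower genes at 5 µM, 1 higher at both levels, and 3 and 7 from 5 to 10 µM. The Twist line had 39 higher in that step, the line effect 1124 higher, and the trend difference 21 and 22 (239 and 214 at the 35th). With the median over probe sets the control line had 2 lower at 5 µM, 19 lower at 10 µM, 1 higher and 1 lower at both, and 1 higher in the step. The Twist line had 319 lower at 5 µM, 653 at 10 µM and 293 at both, the difference between lines 543 and 927 lower, and the trend difference 59 lower. ER-associated degradation at 5 µM was then 0.36, the blood, endothelial and fat cell list reversed to -0.065 between lines, and MAP1B in the Twist line at 10 µM to -0.10. Without probe sets that can cross-hybridise the control line had 12 higher at 5 µM, 47 at 10 µM and 7 at both, and the trend difference 180 and 175. Quantile normalization gave 19 lower at 10 µM in the control line and 5 higher at both, and the deposited scaling 5 higher at both. Quality-matched, the Twist line had 331 higher at 5 µM and 306 at both, with ER-associated degradation at 0.34, or 0.32 over members above the floor in the control line. Outside the range of the 4 other arrays were 178 and 109.

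With no filter limma called 832 higher for the line, 3 and 11 for the control trend, 8 and 9 for the Twist trend and 6 and 4 for the difference, as genes held at the floor enter with no spread. With levels coded 0, 1 and 1 it called 2227 lower in the Twist trend and 1565 and 1738 in the difference. Leaving out an array or pair gave 1157 to 3561 higher and 1340 to 3682 lower for the line, 0 to 1468 and 0 to 1756 for the Twist trend, and 0 to 1021 and 0 to 1174 for the difference. The trend fits leave 1 residual degree of freedom whichever array is left out, and their counts of 0 came without any array but the Twist 5 µM array.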

Other observations

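No test in this part was chosen after a result was seen, as it gives values only.

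From 5 µM to 10 µM in the Twist line, mesenchymal, extracellular matrix and cell cycle lists shifted down by small amounts. Of 25 measured mesenchymal genes 23 lay below their 5 µM value at 10 µM, 2 of them by 2-fold, with a median of -0.24, below all 10000 random lists. PDGFRA, a growth factor receptor of mesenchymal cells, had a step of -2.13 and the collagen gene COL1A2 one of -1.01. Of 18 extracellular matrix genes 14 lay below, 0 by 2-fold, with a median of -0.16 (0.76th percentile), among them LUM, encoding lumican (-0.80), and THBS1, encoding thrombospondin (-0.68). Of 25 cell cycle genes 20 lay below, 0 by 2-fold, with a median of -0.13 (0.33rd percentile), led by the mitotic kinesin gene KIF20A (-0.93). Epithelial lists are largely at or near the floor in this line. Their medians were -0.26 over 5 measured basal genes (1.31st percentile), of which KRT14 and CDH3 lay near the floor, -0.18 over 9 junction genes (4.08th, inside the middle 95% of random lists) and 0.10 over 5 luminal genes (72.3rd). These genes were chosen after their values were seen, and the step is between 1 array and 1 array.

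Outside the lists, some genes of the Twist line went on in the same direction over both levels. HSPA6, an inducible heat shock gene, was higher by 1.25 and 3.05, while the cytosolic heat shock list had a median of -0.08 at 10 µM. SERTAD4 had changes of -2.04 and -4.03. C11orf96, at the floor under DMSO and in the control line, was higher by at least 2.88 and 5.44. These 3 genes were also chosen after their values were seen.

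In the control line 8 of 10 basal genes lay below their DMSO value at 10 µM, 0 of them by 2-fold, and SFN and TRIM29 lay above it by 0.26 and 0.22. KRT5 and CDH3 of the basal list had changes of -0.79 and -0.67 at 10 µM, the integrin gene ITGB4 one of -0.59, and of the luminal list the transcription factor genes FOXA1 and ESR1 had -0.92 and -1.11. The larger epithelial junction and mesenchymal lists did not stand apart, with medians of -0.16 and -0.13. These members went with a 3' to middle contrast of 0.84 on the same array against 0.28 under DMSO. Of 514 long noncoding RNA genes in the Twist line, 50 were higher and 52 lower past 2-fold at 10 µM. For protein-coding genes there the counts were 864 and 918 of 10703. In the control line they were 7 and 0 of 521 long noncoding RNA genes, and 11 and 31 of 10977 protein-coding genes.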
